A study of Mus musculus with 8 samples.

How the data were processed

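RNA from laser-captured lower crypts of the jejunum of 8 mice was labelled with Cy5 and hybridised to Agilent whole-genome mouse arrays, 1 array per mouse, per the labels' protocols. The deposited scanner files hold spot intensities in linear units, extracted by the authors with Agilent Feature Extraction 11.5.1.1, per the file headers, as a background-subtracted processed signal with mean and background signals beside it. The authors' deposited matrix holds log2 values of the same arrays. Its ranks follow the processed signal within every array (Spearman correlation of at least 0.999 across probes), its column medians run from 7.73 to 8.33, and how it was scaled and centred stays unknown. No array pair among 28 held identical values.

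Control spots were left out, leaving 43020 of 44397 spots and 39429 probes after spots of a probe were averaged. Spots flagged as outliers were left out on each array, which cost 2 to 146 probes. No probe was saturated. Of these probes 27655 were named through their accession in a RefSeq gene table of assembly GRCm38.p6, used for names only, and 11774 kept the name in the files. Probe positions are those of the files, in mm9. Between 53.2% and 65.6% of probes were well above background per array. The log2 processed signal minus each array's 75th percentile was tested. Probes had to be well above background on at least 4 of 8 arrays, and the brightest probe stood for a gene, which left 19528 genes. A fold against a group in which no array was well above background is a bound, taken against the higher of the dim signal and the lowest signal among probes well above background on each array.

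Genes were tested with limma 3.58.1 (lmFit, and eBayes with a mean trend) in R 4.3.3, with group and labelled sex as terms and a Benjamini-Hochberg threshold of 0.05. The same model gave the labelled sex difference, and a group by sex term the interaction. Of 47 gene lists for cell types, DNA damage, proliferation, signalling, fasting metabolism, growth and stress, 46 had at least 5 measured members. They were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry as alternatives. A score per array, the mean z-score of a list's genes, was compared by an exact 2-sided permutation test over all splits into 4 and 4. Designs, lists, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined, and the trend of variance with mean in camera was set after a first look at them. That rule takes the 15 genes with the largest difference past the threshold in each direction, filled by smallest unadjusted p where fewer pass and leaving out names that are not gene symbols. It adds up to 4 members with the smallest p from each called or central list, and Lgr5, Olfm4, Ascl2, Lyz1, Muc2, Cdkn1a, Mdm2, Bbc3, Bax, Cpt1a, Pdk4, Top2a and Mki67. Some genes that the rule takes are not reported here. Lgr5, Pdk4 and Top2a failed the filter, Pdk4 being well above background on 0 fasted arrays and 1 fed array.

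The gene test was tested on 20 simulated sets of 19348 genes that kept the real covariance between genes, with 200 genes changed. The simulated arrays were drawn independently, so likeness between arrays of a shared slide was not kept. It recovered 12.0% of genes changed by 1 on the log2 scale, 47.2% of those changed by 2 and 68.2% of those changed by 3. In the same sets camera at the preset correlation called a median of 16 of 46 lists that held no difference, and at an estimated correlation 0. With independent genes it called a median of 0. Other alternatives were quantile and median scaling, normexp background correction with an offset of 50, the authors' matrix, other filters and probe rules, no sex term, slide or replicate number as a block, array weights, other variance models, a threshold of 0.1, and leaving out each array. Slide or replicate number as a fixed block took the place of the sex term. Slides were read from the files: 3 slides held a fasted and a fed array each, and 1 fasted and 1 fed array were alone on theirs. Fasted replicate 3 was the only array of the later scan day.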

Results

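The data are 8 single-colour microarrays of RNA from the lower crypts of the mouse jejunum, 1 array per mouse. The lower crypt is the base of the intestinal gland, where stem cells and antimicrobial Paneth cells lie side by side, and it was cut out of fixed sections by laser capture microdissection. The mice carried a reporter in Lgr5, a gene marking crypt base stem cells, and were 4 to 6 weeks old. All 8 received 80 mg/kg etoposide, a topoisomerase II poison that breaks DNA, and tissue was taken 3 h later. A group of 4 mice had been fasted for 24 h before the injection and the other 4 had been fed. Each group was labelled as 2 males and 2 females. All mice had moistened food after the injection. The fasted arrays thus come from mice offered food again before sampling, and fasting cannot be told apart from refeeding after it. No array came from a mouse without etoposide, so the values compare feeding states after the drug and give no response to the drug itself. The share of probes well above background was 61.0% ± 5.33 (SD, n = 4) on the fasted arrays and 58.4% ± 4.78 (SD, n = 4) on the fed arrays. Fasted replicate 3 stood apart, with correlations across genes of 0.827 to 0.925 to the other arrays. The number of arrays limits the precision of every difference.

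The first comparison asked how lower crypts of fasted and fed mice differed 3 h after etoposide. The genes with the smallest p on the fasted side included Gk, the glycerol kinase, Dgat2, which makes triglyceride, Hsd17b4, a peroxisomal enzyme of fatty acid oxidation, and Fbp1, an enzyme of gluconeogenesis. Gk was 3.78-fold higher in fasted crypts (log2 difference 1.92, SE 0.32), with a mean of 0.00 ± 0.52 (SD, n = 4) against -1.92 ± 0.37 (SD, n = 4) on the log2 scale relative to each array's 75th percentile. Dgat2 was 2.77-fold higher (log2 difference 1.47, SE 0.26). On the fed side the smallest p belonged to Olfm4, a marker of crypt base stem cells, at a log2 difference of -1.11 (SE 0.24), with 1.82 ± 0.63 in fasted and 2.93 ± 0.41 in fed crypts (SD, n = 4 each). None of these values passed the test over all genes. In limma's test 0 of 19528 genes passed the Benjamini-Hochberg threshold of 0.05, the smallest adjusted p was 0.788, and 1161 genes had an unadjusted p under 0.05 where chance alone gives 976. With slide as a block in place of the sex term, 0 genes passed, the smallest adjusted p was 0.114 and 2555 genes had an unadjusted p under 0.05. That fit rests on the 3 slides shared by both groups, with 2 residual degrees of freedom, and differs from the main fit in both terms.

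The 15 genes with the smallest p in each direction are therefore given as values that did not pass. On the fasted side Prkg2 had the smallest p of the 15, ahead of Gk, and a log2 difference of 1.60. Ccnjl was at 1.40, Ephx2 at 1.34, Tmem37 at 1.23, Galnt15 at 1.44, Gstm1 at 1.26, Mmp10 at 1.75, Cbr1 at 0.99 and Pepd at 1.00. Hsd17b4 was at 1.37 and Fbp1 at 1.29. Akr1e1 and Cbfa2t2 were not well above background on any fed array, so their folds are bounds: at least 3.12-fold and at least 2.81-fold higher in fasted crypts, with an adjusted p of 0.788 for each. On the fed side, Tmprss13 had a log2 difference of -2.17, Ank3 -1.17, Defb34 -1.43, Il15ra -0.52, Col27a1 -1.84, Pip5k1a -0.84, Nupr1 -0.91, Defa38 -0.53, Gcm1 -0.55, Exosc9 -0.67, Susd3 -0.91, Hmgn2 -0.57, Lgals1 -0.70 and Col7a1 -0.75. In 4.93% of genes all 4 fasted arrays lay on one side of all 4 fed arrays, where chance gives 2.86%. The probe for Gk lies on chromosome X from 82956390 to 82956449, that for Dgat2 on chromosome 7 from 106302215 to 106302274 and that for Olfm4 on chromosome 14 from 80421398 to 80421457, in the mouse build mm9 named in the file headers.

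**Figure D1:**
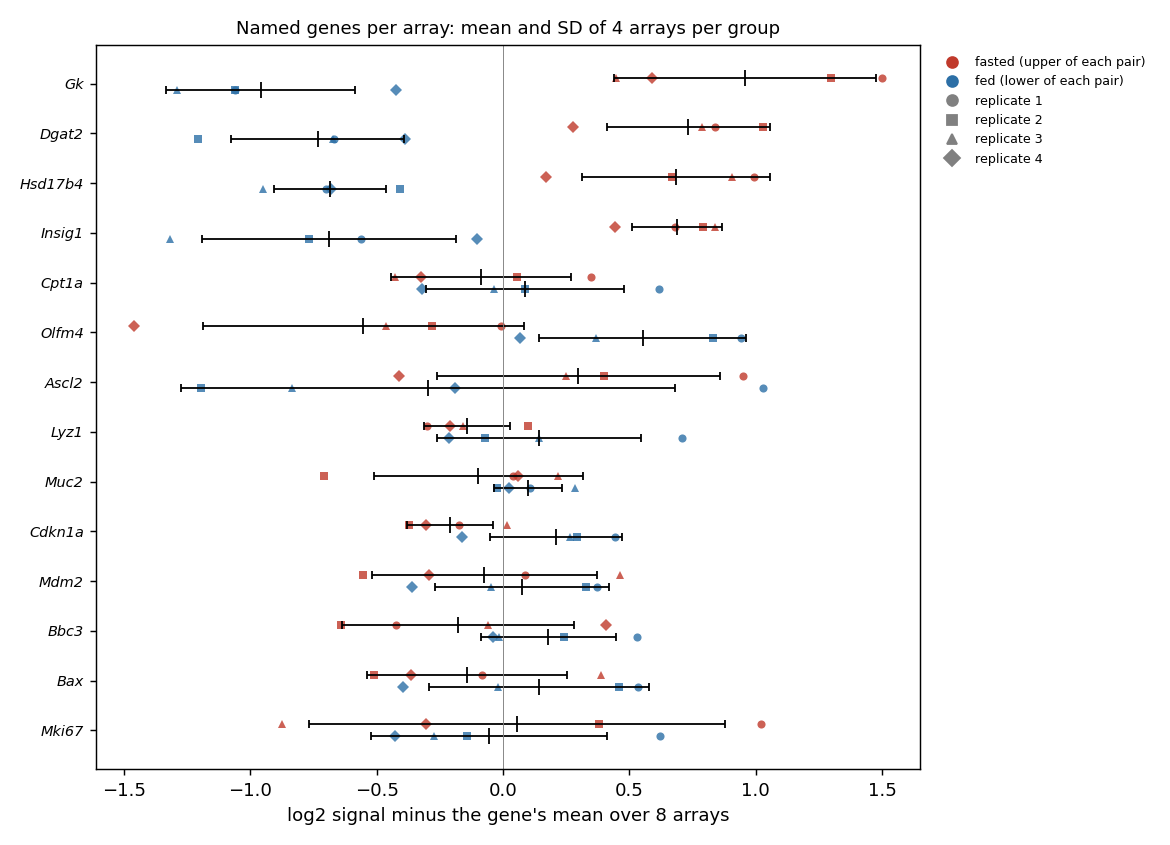
Log2 signal of 14 genes in each of the 8 arrays, relative to the gene's mean over all arrays (horizontal axis), with fasted arrays in red above fed arrays in blue, marker shape for the replicate, and the mean and SD of 4 arrays in black. Gk, Dgat2, Hsd17b4, Insig1 and Olfm4 separate the groups, the p53 targets Cdkn1a, Mdm2, Bbc3 and Bax overlap, and no gene passed the test over all genes.

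Markers of absorptive enterocytes, the nutrient-absorbing cells that mature above the crypt base, stood highest in fasted crypts among the gene lists. Of 33 measured members 31 were higher, with a median log2 difference of 1.06. Enpep, Mep1b and Slc7a9, which are brush border peptidases and an amino acid transporter, differed by 1.92, 1.73 and 1.17. No member passed over all genes, 12 passed when adjusted over the list alone, and 15 separated the groups. With limma's camera at a preset inter-gene correlation the list passed (adjusted p = 3.45e-21), and it did not with an estimated correlation (adjusted p = 0.34). The per-array score gave an exact 2-sided permutation p of 0.0286, the smallest that 4 against 4 can give, and 0.376 after adjustment over 46 lists. An adjusted value under 0.05 would have needed most of the 46 lists to reach that smallest p. Within the 3 slides that held a fasted and a fed array the medians were 1.25, 1.31 and 0.66, and the median was 1.08 with slide as a block.

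Lipid and glucose genes lay higher in the same fasted arrays. In sterol and fatty acid synthesis 35 of 39 measured genes were higher (median log2 difference 0.62), led by Insig1 at 1.38, Lss, the lanosterol synthase, at 2.39 and Fdft1 at 1.30, with 9 passing when adjusted over the list alone. Lss was well above background on only 2 fed arrays and differed by 3.40, 2.64 and 0.67 within the 3 shared slides. Among PPAR alpha targets and fatty acid oxidation genes 37 of 43 were higher (median 0.53), with Acaa2 at 1.25 and Ehhadh at 1.18, and 0 passed over the list alone. Cpt1a, which admits fatty acids to mitochondria, differed by -0.17 (SE 0.23). Gluconeogenesis genes were higher in 13 of 18 (median 0.45), including Got1 at 0.89, and 1 passed over the list alone. These 3 lists passed at the preset correlation, with adjusted p of 4.24e-14, 8.13e-12 and 0.000193. With an estimated correlation the adjusted p were 0.34, 0.459 and 0.405. The within-slide medians were 0.70, 0.88 and 0.13 for sterol and fatty acid synthesis, 0.45, 0.58 and 0.37 for fatty acid oxidation, and 0.51, 0.51 and 0.34 for gluconeogenesis. Slide as a block gave medians of 0.58, 0.52 and 0.53. The enterocyte markers were higher in these same arrays, as given above.

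Paneth cell markers were lower in fasted crypts in 16 of 18 measured genes (median -0.42). Pla2g2a differed by -0.80, Defa3 by -0.49 and Lyz1, the Paneth cell lysozyme, by -0.28, and 0 members passed over the list alone. Over the alternatives Defa3 ranged from -0.64 to -0.074 and Lyz1 from -0.413 to -0.05, so both came near 0. Pla2g2a ranged from -1.169 to -0.548. With normexp and quantile normalization the median was -0.174 and the list did not pass (adjusted p = 0.0641). Immediate early genes, which respond within minutes to stimulation, were lower in 31 of 35 (median -0.42), with Egr3 at -1.36, Atf3 at -1.53 and Fosl2 at -0.59, and 0 passed over the list alone. The adjusted p were 0.000193 and 0.000201 at the preset correlation, and 0.34 and 0.713 with an estimated correlation. The within-slide medians were -0.78, -0.54 and -0.04 for Paneth cell markers, and -0.79, -0.79 and -0.07 for immediate early genes. With slide as a block the medians were -0.40 and -0.55. With the share of probes well above background as a covariate the immediate early genes moved to a median of -0.245 and did not pass (adjusted p = 0.231). Their per-array score was -0.897 and -0.867 in fasted replicates 1 and 2, -0.216 in fasted replicate 4 and 0.772 in fasted replicate 3. The fed scores ran from -0.199 to 0.72, and the exact permutation p of the score was 0.229.

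Crypt base stem cell markers did not pass as a list: 11 of 23 measured genes were higher and 12 lower, with a median of -0.05 and an adjusted p of 0.517. The median turned to 0.192 without fed replicate 1, and to -0.261 without fasted replicate 3, where the list passed at the preset correlation (adjusted p = 0.0453). Ascl2, a transcription factor of these stem cells, differed by 0.59 (SE 0.46), and Olfm4 was the 1 member that passed when adjusted over the list alone. Lgr5 was not well above background on any array. The 10 reserve stem cell markers split into 5 higher and 5 lower (adjusted p = 0.938). Goblet cell markers had a median of -0.19 (adjusted p = 0.219), with Muc2, the main mucin, at -0.20 (SE 0.20), and enteroendocrine and tuft cell markers had medians of 0.17 and 0.08 (adjusted p = 0.814 and 0.461). Markers of cells outside the epithelium did not pass: the medians were -0.11 for fibroblast and smooth muscle, -0.16 for endothelial, -0.12 for leukocyte, -0.07 for enteric neuron and glia, 0.30 for erythroid and -0.40 for pancreatic acinar genes.

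Genes of the DNA damage response showed no difference past the threshold in most lists. Of 56 measured p53 targets 42 were lower in fasted crypts, with a median of -0.18 and an adjusted p of 0.0693. With slide as a block in place of the sex term the median was -0.23 and the list passed at the preset correlation (adjusted p = 0.000765), while the share of probes well above background as a covariate gave -0.04 (adjusted p = 0.635) and an estimated correlation an adjusted p of 0.855. Cdkn1a, the p21 cell cycle inhibitor, differed by -0.42 (SE 0.18), Mdm2, which degrades p53, by -0.15 (SE 0.27), and the apoptosis genes Bbc3 and Bax by -0.36 (SE 0.26) and -0.29 (SE 0.28). Pro-apoptotic and anti-apoptotic genes had medians of 0.05 and -0.01 (adjusted p = 0.97 for both). Homologous recombination, checkpoint, Fanconi anaemia, and excision and mismatch repair genes had medians of 0.11, 0.23, 0.17 and 0.03, with adjusted p of 0.413, 0.118, 0.24 and 0.237. Non-homologous end joining, which rejoins broken DNA ends, was the repair list that passed at the preset correlation (16 of 20 higher, median 0.46, adjusted p = 0.000514), and its adjusted p was 0.34 with an estimated correlation. Its members Xrcc6, Trp53bp1 and Parp1 differed by 0.56, 0.84 and 0.76, 0 members passed over the list alone, and the list's within-slide medians were 0.39, 0.20 and 0.25. Within the same slides Xrcc6 differed by 0.64, 0.69 and 0.53, Trp53bp1 by 1.54, 0.12 and -0.04 and Parp1 by 0.78, 1.22 and 0.03. Mitosis genes were lower in 26 of 35 (median -0.21, adjusted p = 0.0577) and passed in 10 of 29 alternatives, Mki67, a proliferation marker, differed by 0.11 (SE 0.30), and Top2a, the target of etoposide, was not well above background on any array.

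**Figure D2:**
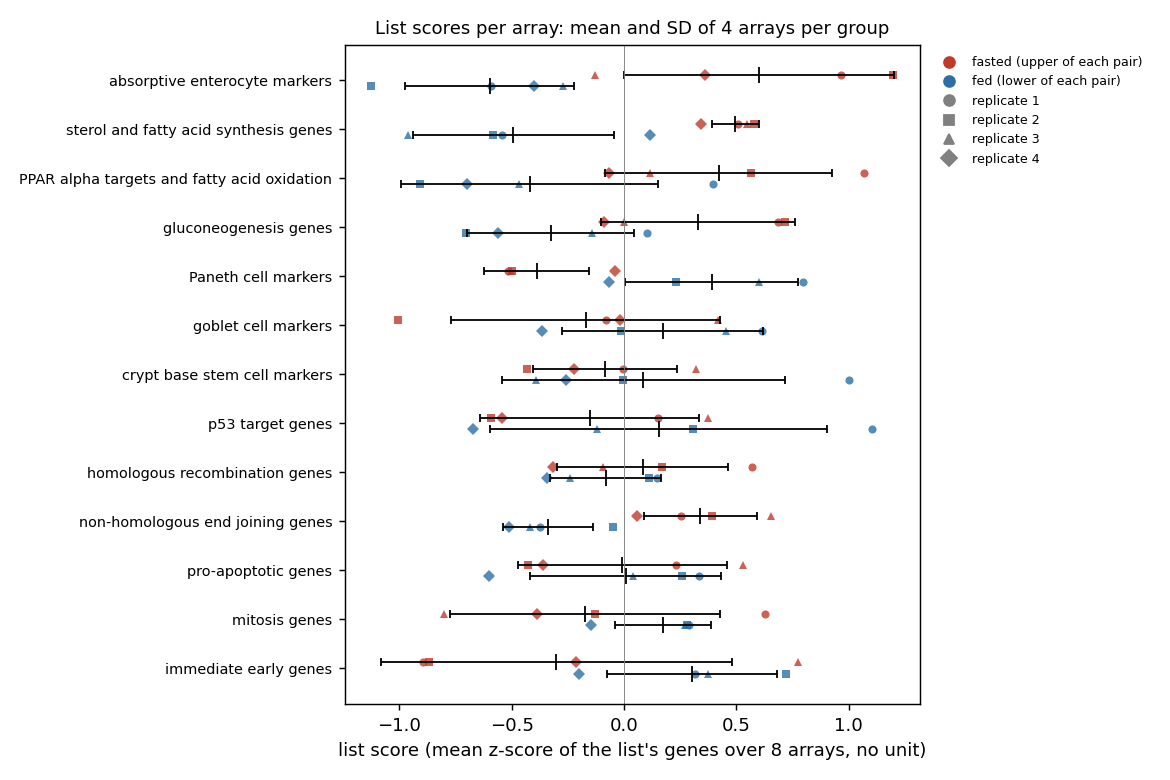
Score of 13 gene lists in each of the 8 arrays (horizontal axis, mean z-score of the list's genes, no unit), with fasted arrays in red above fed arrays in blue, marker shape for the replicate, and the mean and SD of 4 arrays in black. All 4 fasted arrays exceed all 4 fed arrays for enterocyte markers, sterol and fatty acid synthesis and non-homologous end joining, while stem cell, p53 target and apoptosis scores overlap.

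In all, 16 of 46 lists passed at the preset correlation, 12 higher and 4 lower in fasted crypts, and 0 passed with an estimated correlation or with fry. Whether either of the latter tests can call a list that does differ was not simulated, so their 0 does not show that no list differs. The 16 lists are no more than regrouping gives: the 34 other splits of the 8 arrays called a median of 15 lists and up to 22. Simulated arrays with the real gene covariance and no difference in any list gave a median of 16. Those arrays were independent, whereas real arrays of a shared slide deviated together with correlations of 0.372, 0.536 and 0.606. Without fasted replicate 3 and fed replicate 4, a fit not set against its own splits, 22 lists and 0 genes passed. The preset correlation of 0.01 lay below the median estimate of 0.169, so the preset-correlation p-values above are too small for these arrays and do not separate feeding state from chance. For the enterocyte list alone, 2 of 35 splits, the real one included, gave a camera p as small as the real one, which is not a share under 0.05. The other split kept fasted replicates 1, 2 and 4 together and exchanged fasted replicate 3 for fed replicate 1. It thus holds most of the real grouping, so this share does not decide between feeding state and chance.

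**Figure D3:**
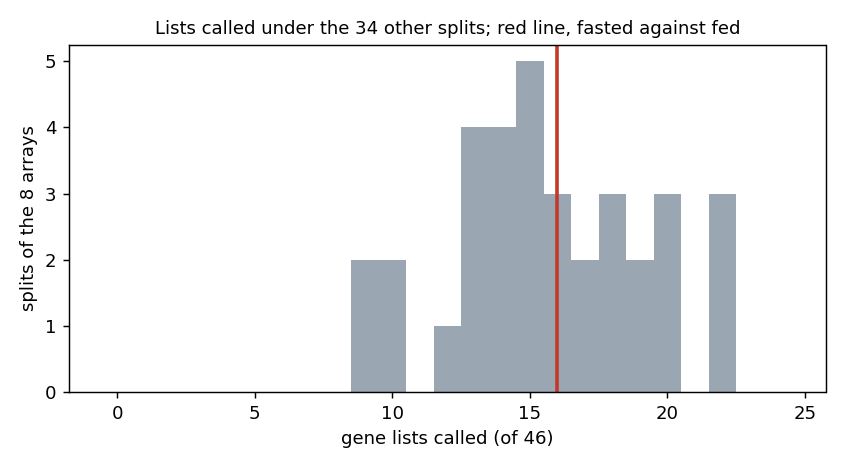
Number of gene lists called at the preset correlation (horizontal axis) in each of the 34 other splits of the 8 arrays into 4 and 4 (vertical axis, number of splits), with the red line at the 16 lists called for fasted against fed. The real grouping lies near the middle of the other splits.

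The second comparison asked whether the difference between feeding states depended on the labelled sex. Reg3b, an antimicrobial lectin, was the 1 gene that passed when fed replicate 2 was left out, a fit in which fed replicate 1 is the only fed array labelled male and is assumed to vary like the rest. With all arrays, limma's interaction test called 0 of 19488 genes, the smallest adjusted p was 0.758, and 625 genes had an unadjusted p under 0.05 where chance gives 974. Leaving out fasted replicate 4 brought the count to 2226, a fit in which fasted replicate 3 is the only fasted array labelled female and is assumed to vary like the rest.

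The third comparison set arrays labelled male against arrays labelled female. Xist, the transcript that silences an X chromosome in females, had log2 signals of 13.09, 13.38 and 13.69 in 3 arrays labelled female and 4.69, not well above background, in the array labelled female as fed replicate 4. That array also held Eif2s3y, a Y-linked gene, at 9.31, against 5.05 to 5.29 in the other arrays labelled female and 7.29 to 9.79 in those labelled male. Its transcripts thus contradict its label, and values by labelled sex carry that array. The main feeding test, which holds labelled sex as a term, carries the label too. If the transcripts are right, the fed group was not balanced for sex, and no fit with the label changed was run. The Xist probe was well above background on only those 3 arrays, so it did not pass the filter and was not tested. The probes for the Y-linked Kdm5d, Ddx3y and Uty did not pass it either. Among the genes tested, limma's test called 0 of 19528 for labelled sex. An unadjusted p under 0.05 was found for 442, where chance gives 976. Without fasted replicate 3, 5 genes passed, Gm17783, Ceacam20, Snrnp27, Olfr1428 and Anapc11, named here after their values were seen.

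**Figure D4:**
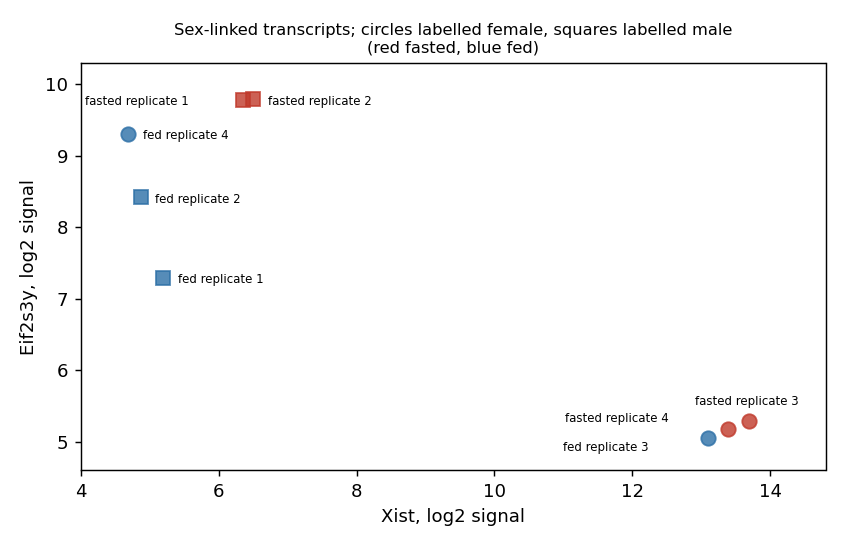
Log2 signal of Xist (horizontal axis) and Eif2s3y (vertical axis) in each array, circles for arrays labelled female and squares for arrays labelled male, red for fasted and blue for fed. Fed replicate 4, labelled female, lies with the arrays labelled male, at 4.69 for Xist and 9.31 for Eif2s3y.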

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

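The tests of the sex label, of slides, of brush border genes and of splits within slides were chosen after the results were seen. The 35 splits were planned, and the test of signal over background was added after the enterocyte values were seen and before its own result was. The array labelled female as fed replicate 4 held the Y-linked gene Eif2s3y well above background, which none of the other arrays labelled female did, and lay 4.14 log2 units above their dim signals. Kdm5d, also Y-linked, lay 2.19 above them but was not well above background on any array labelled female, so it decides nothing. An exchange with another mouse of the series would leave Xist on an array labelled male, and 0 such arrays held it. That does not test whether a male mouse of the series was sampled a second time. A mixture of male and female RNA would keep Xist visible, and its signal, not well above background, lay 8.4 log2 units below the lowest of the other arrays labelled female. A single wrong sex entry, a second sample of a male of the series, or tissue of a mouse from outside the series could account for it and stays open. The feeding label of that array has no test of its own.

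Enterocyte markers were higher in fasted captures. A difference between slides is argued against by the arrays that share one: the lowest of the 3 within-slide medians was 0.66. Signal over background did not account for it as a linear covariate: with the share of probes well above background fitted, the median was 0.90. On each of the 3 shared slides the fasted array had the higher share (60.9 against 53.2%, 65.6 against 62.2% and 63.9 against 62.8%). The within-slide medians thus do not separate feeding state from signal level. Across the 8 arrays the enterocyte score and that share had a Pearson r of 0.636 (exact permutation p = 0.0947) and a Spearman rho of 0.595 (exact permutation p = 0.132), the 1 relation computed, and r was 0.717 without the 2 arrays farthest from the median. Cells from above the lower crypt in the captures may be a source, and no value here decides it: the 18 measured brush border genes (median 1.15) belong to the list, so they repeat what it showed. A change of expression inside the crypt after fasting, or after the food that followed it, would look the same. Chance stays open too, since the list's adjusted p was 0.34 with an estimated correlation.

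Over all splits the number of lists and genes does not exclude chance. Of the 35 splits of the 8 arrays, 17 called at least the real 16 lists, and the highest other split called 22. For genes at an unadjusted p under 0.05, 7 of 35 splits reached the real 1161, and the highest other had 6778. Many of these splits do not keep the slides balanced. Among the 8 that part each of the 3 shared slides, the real one was the highest for genes (the highest other had 611), and 4 called at least 16 lists. With slide as a block the real grouping had 2555 genes and the highest other 845, among 4 groupings. These splits are too few for a share under 0.05. The real comparisons called 0 genes for feeding and 0 for labelled sex, so all 35 splits had to give as many, and these counts tell nothing about chance. The highest others called 3395 and 2627. The split with 3395 parts the 4 arrays on the slides of fasted replicates 2 and 4 from the other 4, which points to a structure of the arrays. The same 4 arrays also had the highest shares of probes well above background (62.2 to 65.6% against 53.2 to 60.9%), and no test separated slide from signal level. With slide as a block 0 genes passed for feeding.

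Of 174 groups of 4 arrays tested for 1 array far from the rest, 7 exceeded Dixon's critical ratio, where chance gives 8.7. These ratios of gap to range were 0.958 for the Paneth cell score of fasted replicate 4, 0.933 for the fibroblast and smooth muscle score and 0.954 for the mitosis score of fed replicate 4, 0.848 for the ribosome biogenesis score of fasted replicate 3, 0.897 for the antimicrobial and secreted defence score of fed replicate 1, 0.901 for Galnt15 in fed replicate 1 and 0.853 for Defb34 in fasted replicate 4.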

How the results depend on the processing

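Leaving out fasted replicate 3 with fed replicate 4, and the share of probes above background as a covariate, were added after the data were seen, the covariate before its own result was. Genes called for feeding stayed at 0 in every alternative run. List scores did too, but their exact permutation test could hardly give another count. Its smallest p of 0.0286 passes after adjustment over 46 lists only if most lists reach it. Lists called ranged from 14 to 22 across the alternatives that kept camera's preset correlation (15 to 21 with 1 array left out). They were 0 with an estimated correlation, where the correlation between genes enters the test. With fry, which also tests a list on its own and not against other genes, they were 0 too. Replicate numbers did not pair the arrays: same-numbered arrays deviated together with correlations of 0.372, -0.469, -0.446 and 0.606. The replicate block gave 0 genes and 19 lists. Slide as a fixed block in place of the sex term gave 15 lists, with p53 targets, goblet cell markers and class II genes gained and glycolysis, ribosome biogenesis, unfolded protein response and amino acid response genes lost. With 1 array left out, genes called by labelled sex ran from 0 to 5 and genes called for the interaction from 0 to 2226; the cause was not tested. The ribosomal protein list turned from a median of -0.22 to 0.035 with quantile normalization, 0.033 with normexp and quantile normalization and 0.003 with the authors' matrix, and ribosome biogenesis from 0.15 to -0.014 without fasted replicate 3 (0.257 without fed replicate 2). The cause was not tested. Paneth cell markers lost their call with normexp and quantile normalization (median -0.17, adjusted p = 0.0641, range over alternatives 7.23e-06 to 0.34). In 29 alternatives the call ended 17 times for amino acid response genes, 8 for glycolysis, 6 each for unfolded protein response and ribosome biogenesis genes, 4 for DNA replication, 3 each for Paneth cell markers, immediate early genes and NRF2 targets and 2 for each of the other 8 lists, and was gained 12 times for proteasome genes, 11 for p53 targets, 10 for mitosis genes (lowest adjusted p = 0.00028), 6 for interferon response genes and 1 to 4 times for 12 other lists. The gained calls leave out alternatives in which a list's median had the opposite sign. In such alternatives pro-apoptotic, FoxO and clock genes also passed, with lowest adjusted p of 0.0448, 0.032 and 0.0447. Of 4998 values of 187 named genes under alternatives, 26 had the opposite sign and none passed. Signal over background limits what can be seen of Lgr5 and Top2a.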

Other observations

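Clock genes held some of the larger single differences outside the lists above. Per2, Per3 and Usp2 had log2 differences of 2.91, 1.57 and 1.38 in fasted against fed crypts, none past the threshold over all genes. Per2 was well above background on only 2 fed arrays and differed by 1.40, 5.47 and -0.04 within the 3 shared slides. The list of 18 measured clock genes had a median of -0.10 and a mean of 0.24, which differ in sign (adjusted p = 0.216). Cytosolic ribosomal proteins were lower in 73 of 77 genes (median -0.22), a direction that turned with quantile normalization, and ribosome biogenesis genes were higher in 49 of 68 (median 0.15), a direction that turned without fasted replicate 3. Heat shock genes were higher in 18 of 23 (median 0.32), with Hsph1 at 1.60, NRF2 targets in 23 of 35 (median 0.21), unfolded protein response genes in 31 of 43 (median 0.28), glycolysis genes in 16 of 21 (median 0.15), DNA replication genes in 36 of 48 (median 0.21) and etoposide target and transport genes in 12 of 16 (median 0.30). Amino acid response genes were lower in 27 of 43 (median -0.22), a call that ended in 17 of 29 alternatives. Within the 3 shared slides DNA replication genes had medians of 0.32, 0.42 and -0.11, and 1 slide also went against the direction above for ribosomal proteins (0.03), unfolded protein response genes (-0.001) and amino acid response genes (0.05). All 9 of these lists passed at the preset correlation and none with an estimated one, where adjusted p ran from 0.34 to 0.817. FoxO, glucocorticoid, autophagy and oxidative phosphorylation genes had medians of 0.06, -0.08, 0.00 and -0.06 and did not pass. Wnt, Notch, interferon, class II, antimicrobial and proteasome genes had medians of 0.01, 0.13, 0.19, -0.36, -0.34 and 0.14 and did not pass.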
